A study of Homo sapiens with 25 samples.

How the data were processed

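MicroRNA was profiled on Agilent single-colour (Cy3) miRNA arrays in 25 samples of sorted human B cells, 18 from follicular lymphoma and 7 from follicular hyperplasia. Per the labels, 100 ng of total RNA was labelled for each array. Groups and replicate numbers were taken from the sample titles. The labels mark the samples as separate but do not say more about their origin, so p-values measure the spread between these samples. No 2 arrays held identical values, and the highest correlation between arrays was 0.978 within hyperplasia and 0.985 within lymphoma, so each array counted as 1 replicate.

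Each array had 15739 spots, of which 15024 were not controls. They carried 2689 probes for 939 miRNA names (851 human, 88 viral), with 4 to 16 spots per probe and 1 to 4 probes per miRNA. Agilent Feature Extraction 10.7.3.1 was used, per the submitters' processing notes. The spot signal is an intensity on a linear scale, already detrended over the array and background-subtracted, per the file headers. The deposited total signal per miRNA is also an intensity, summed over the probes of a miRNA and set to a small constant where the miRNA was not detected. The deposited value table is on a log2 scale. Set against the total signals, each of its columns equals the log2 of the total signal (values under 1 set to 1) minus 1 constant per array, with a median from -9.33 to -6.55 over the 25 columns. The origin of that constant stays unknown, while the scale and direction are clear. Of 961 names in that table, 924 matched miRNAs in the scanner files and 15 miRNA names did not.

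For the main values, control spots and spots with an outlier flag were left out, and the processed signals of the spots of a probe were averaged. Fewer than 1 in 2 probes were detected, so each array was divided by the 75th percentile over the 102 probes that were well above background on all 25 arrays. A common floor was then set (0.00572 on the scaled signal, -7.45 on the log2 scale), the median over arrays of the 5th percentile among probes well above background. The log2 values were averaged over the probes of a miRNA. Among the named miRNAs, the probes of miR-28-3p disagreed in sign. Signals at the floor carry no order, and no fold is given for a miRNA that lay at the floor on most arrays of a group. A lower bound of a fold ("at least") sets the mean of the detected group against the mean, per array of the other group, of the highest of the common floor, the lowest signal well above background and the probe's own. No bound was given where it fell under 1, or where the mean of the detected group lay below the mean limit of that group's own arrays. The number of arrays limits the precision.

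Human miRNAs detected on at least 7 of 25 arrays (347) were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 18 lists (miRNA families, B cell and lymphoma lists, markers of other cell types, and GC-rich miRNAs) were compared by counts, and 17 with at least 3 tested members by camera with a preset correlation of 0.01. The calls of 3 lists (let-7, p53-induced and epithelial) were made so, and 0 of 17 held with an estimated correlation. fry, which tests a list without setting it against other miRNAs, was also set in advance. The fry adjusted p was under 0.05 for the epithelial (4.53e-07), miR-30 (3.08e-06), B cell differentiation (0.000807), germinal centre (0.00364), miR-17 (0.0114) and p53-induced (0.0174) lists. The let-7 list and all others had 0.0867 or more. Single values per array were compared by an exact permutation test over all 480700 splits. Samples, tests, lists, the rule for named miRNAs and most alternatives were set before the data were examined. The rule names the 12 largest rises and the 12 largest falls among called miRNAs whose sign held whichever array was left out, the 5 with the highest mean signal in each group, and from each list up to 4 called members with the smallest p. Names are those of the array's design, which can be old, and entries of near-identical families (let-7, miR-320, miR-181, miR-30) are uncertain because their probes may share signal. No coordinates are given, since the files name no genome build. Probes for viral miRNAs were summarised by detection. The 21 viral names detected on at least 7 arrays were also tested with limma, which had not been set in advance.

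The test was tried on simulated arrays that had the real probe means, spreads and array brightness, for the lymphoma against hyperplasia comparison, in 20 runs for each of 3 designs. A first version gave signal to every probe, so that a median of 653 miRNAs entered the test instead of 347, and changed 60 miRNAs, 20 each by 2-fold, 4-fold and 8-fold. It recovered 43.5%, 75.8% and 82.8% of these, but 69.2% of its calls were false. A stricter version left rarely detected probes without signal (median of 282 miRNAs tested). With 60 changed it recovered 35.2%, 68.5% and 77.8%, with 27.8% of calls false, and with 30 changed (median of 286 tested) it recovered 22.0%, 66.0% and 71.5%, with 22.9% false. The stricter version was written after the result of the first was seen. Across the 3 designs, 97.9% to 99.8% of false calls were falls, and among calls of at least 2-fold 4.80% to 6.10% were false. Simulated arrays with no change gave calls in 8, 3 and 1 of 20 runs (first version, 60 changed and 30 changed), with at most 111, 2 and 1 calls in a run, the first being more than the 76 calls on the real arrays. The threshold of 0.05 therefore understates the share of false calls among small falls, and counts at 2-fold or more were added for that reason. Simulated signals followed array brightness in proportion, and miRNAs varied independently of one another. Background noise was equal on all simulated arrays. On the real arrays the SD of negative controls was 8.75, 5.18 and 3.39 on hyperplasia replicates 6, 8 and 1. It was 1.14 to 1.62 on the other hyperplasia arrays and 1.27 to 2.29 in lymphoma. The shares of false calls, also those at 2-fold or more, therefore do not cover miRNAs whose signal does not follow brightness or that vary together. Nor do they cover noise that differs between the groups.

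The alternatives set in advance were the percentile over all probes, quantile normalization, no scaling, normexp (offset 50) before the main scaling, the deposited total signals, the authors' value table, no filter on dim miRNAs, only the 79 miRNAs detected on all arrays, a lower floor, the slide as a random block, each lymphoma slide alone, the replicate number as a block, trended and robust moderation, and leaving out each array. normexp used median spot signals, because the files analysed here held no mean signal column. For the slide block and the trended fit, lists were tested by camera on the moderated statistics of those fits. Keeping spots with outlier flags, array brightness as a covariate, leaving out 3 or 5 arrays that stood apart, the estimated correlation, and calls of at least 2-fold were added after the data had been seen. Scripts ran under Python 3.11.15 and R.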

Results

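MicroRNA levels were measured in B cells sorted from human follicular lymphoma, a cancer of germinal centre B cells, and from follicular hyperplasia, a benign enlargement of lymphoid follicles that served as the reference. There were 18 lymphoma samples and 7 hyperplasia samples, each on 1 single-colour array with probes for 851 human miRNA names. An array detected 305 ± 57.8 human miRNAs in lymphoma (SD, n = 18) and 202 ± 62.6 in hyperplasia (SD, n = 7), a difference of 103 (exact permutation test over 480700 splits, two-sided p = 0.000659, Benjamini-Hochberg adjusted p = 0.00198 over 6 array measures). The lymphoma arrays were also brighter: their scale factor, the 75th percentile of signal over the probes detected on all arrays, was 4.30-fold that of the hyperplasia arrays (adjusted p = 0.00353, exact permutation test). A hybridization spike-in was 2.06-fold brighter on the lymphoma arrays (adjusted p = 2.5e-05, exact permutation test), while a labelling spike-in did not pass the test (log10 signal 3.56 ± 0.350 in lymphoma and 3.59 ± 0.154 in hyperplasia, SD, adjusted p = 0.876, exact permutation test). All 7 hyperplasia arrays lay on slide 1, and the lymphoma arrays lay on slide 2 (6 arrays), slide 3 (5 arrays) and slide 4 (7 arrays), scanned in another batch than slide 1. The lymphoma slides detected 314 ± 24.9, 244 ± 44.9 and 342 ± 53.1 human miRNAs per array (SD). No slide held both groups. The arrays that stood apart were hyperplasia replicate 6, with 87 detected miRNAs, and lymphoma replicates 8, 9, 14 and 15, with 41.0% to 73.2% of their signal in miR-923. No miRNA took more than 38.3% of the signal on the other 14 lymphoma arrays. The log10 labelling spike-in of these 4 was 2.45 to 3.34. Among the other 14 (3.32 to 3.81) replicate 10 alone lay in that range, and the next, replicate 11, had 3.65. The hyperplasia arrays had 3.375 to 3.774.

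**Figure D1:**
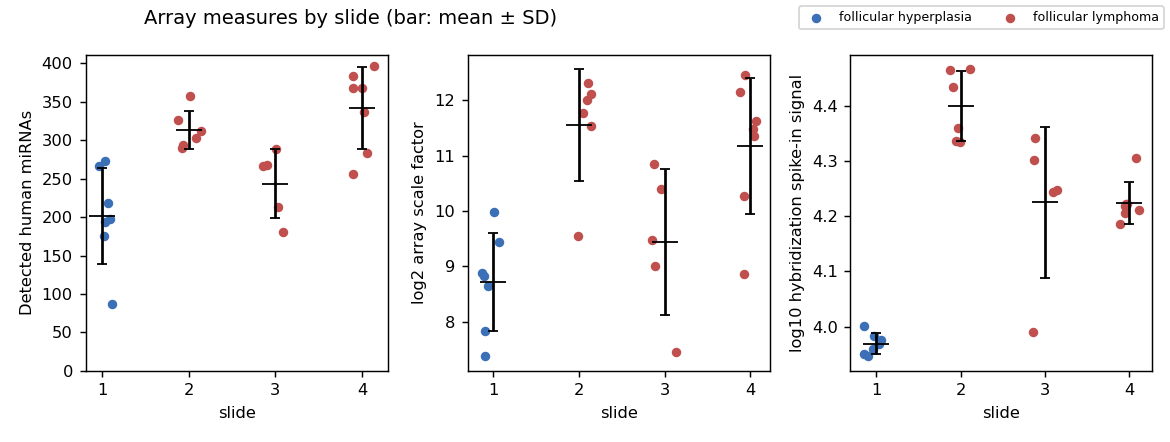
Detected human miRNAs (count), log2 array scale factor and log10 hybridization spike-in signal of each array (points), by slide, with mean and SD (bars). Slide 1 holds the 7 hyperplasia arrays and slides 2 to 4 the 18 lymphoma arrays, and the hyperplasia spike-in values average 3.97 on the log10 scale, against 4.28 in lymphoma.

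The comparison asked which miRNAs differ between B cells sorted from lymphoma and those sorted from hyperplasia. The sample titles name B cells without a subset, so a difference in the mix of B cell subsets was not tested. In lymphoma, miR-374a, which lay at the common floor on 3 of 7 hyperplasia arrays, was 6.27-fold higher, miR-30b was 4.43-fold higher, and miR-34a, a miRNA induced by p53, was 4.64-fold higher. The let-7 family members let-7f and let-7c rose by 5.56-fold and 2.60-fold. miR-374a, miR-34a and let-7c were detected on 3, 4 and 5 of 7 hyperplasia arrays. Their hyperplasia means (-6.85, -6.52 and -6.03 on the log2 scale) lay below the mean limit used for bounds on these arrays (-5.45), so their folds are uncertain. In the opposite direction, miR-141 was 13.6-fold higher in hyperplasia, and miR-205, which was detected on 6 of 7 hyperplasia arrays and on 0 of 18 lymphoma arrays, was at least 7.34-fold higher there, both being miRNAs typical of epithelial cells. miR-17*, from the cluster that also holds miR-92a, was 8.45-fold higher in hyperplasia, miR-30a was 6.57-fold higher, and miR-222 and miR-22 were 5.86-fold and 5.73-fold higher.

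Of 347 human miRNAs tested with limma, 20 were higher and 56 were lower in lymphoma at an adjusted p under 0.05. Of these, 13 higher and 41 lower miRNAs had a fitted change of at least 2-fold. The counts include miR-9*, which 0 of 7 hyperplasia arrays detected, and miR-374b, miR-200b and miR-338-3p. No fold is given for these miRNAs, because each lay at the floor on most arrays of a group. The number of higher miRNAs was 13 without hyperplasia replicate 5, 6 or 8, 31 without lymphoma replicate 9, and 35 (with 77 lower) without hyperplasia replicate 6 and lymphoma replicates 8 and 9. It was 43 (with 100 lower) without lymphoma replicates 14 and 15 as well. On lymphoma replicates 8, 9, 14 and 15 the log2 level of let-7f was -5.50 to -3.16, against -4.79 to -1.44 in hyperplasia and -2.47 to 0.66 on the other 14 lymphoma arrays, and that of miR-15b was -5.25 to -2.80, against -4.38 to -2.54 and -2.67 to 0.15. On the same 4 arrays miR-222 lay at -2.73 to -1.83 (hyperplasia -2.39 to -0.88, other lymphoma -6.20 to -2.71) and miR-320c at -2.57 to -0.998 (-2.62 to -1.46 and -6.26 to -3.28). Their mean level of GC-rich miRNAs was -2.43 to -0.74, against -3.97 to -2.54 in hyperplasia and -6.09 to -3.34 on the other lymphoma arrays. The size of the change matters for the lower calls, because in simulated arrays with the same brightness as the real ones nearly all false calls were falls, most of them under 2-fold. The simulated signals followed array brightness in proportion, miRNAs varied independently, and background noise was equal on all simulated arrays. Larger false falls of miRNAs whose signal does not follow brightness are therefore not covered. Neither are those from the unequal noise of the real arrays. A miRNA was called in the same direction under the main scaling and all 6 other scalings or summaries for 2 higher miRNAs (miR-1274a and miR-1274b) and 5 lower ones (miR-141, miR-17*, miR-30a, miR-200b and miR-431*). Of these 7, miR-431* lost its call with array brightness as a covariate (change of -0.64, adjusted p = 0.246). The median change over all tested miRNAs was -0.06 on the log2 scale. Over the 79 miRNAs detected on all arrays, however, it was -0.98 (4 higher, 37 lower). The called falls of let-7i (-0.69) and miR-25 (-0.55) were smaller than that median, and the fall of miR-106b (-0.98) equalled it. Over all tested miRNAs, the median was 0.53 without scaling (116 higher, 5 lower) and 0.68 with the deposited total signals (94 higher, 25 lower). In the authors' value table it was 1.005 (137 higher, 11 lower). With normexp background correction it was -1.14 (7 higher, 309 lower), with quantile normalization 0.05 (32 higher, 34 lower), and with the percentile over all probes 0.01 (4 higher, 15 lower). Relative to the median over all tested miRNAs in the main and the 6 other scalings or summaries, 53 of the 76 called miRNAs lay on the same side throughout. Among the falls named here, let-7i, miR-106b, miR-92a, miR-25, miR-21, miR-342-3p, miR-30e, miR-30e*, miR-301a, miR-24 and miR-486-5p lay above the median without scaling, with changes of 0.69 to 1.56.

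**Figure D2:**
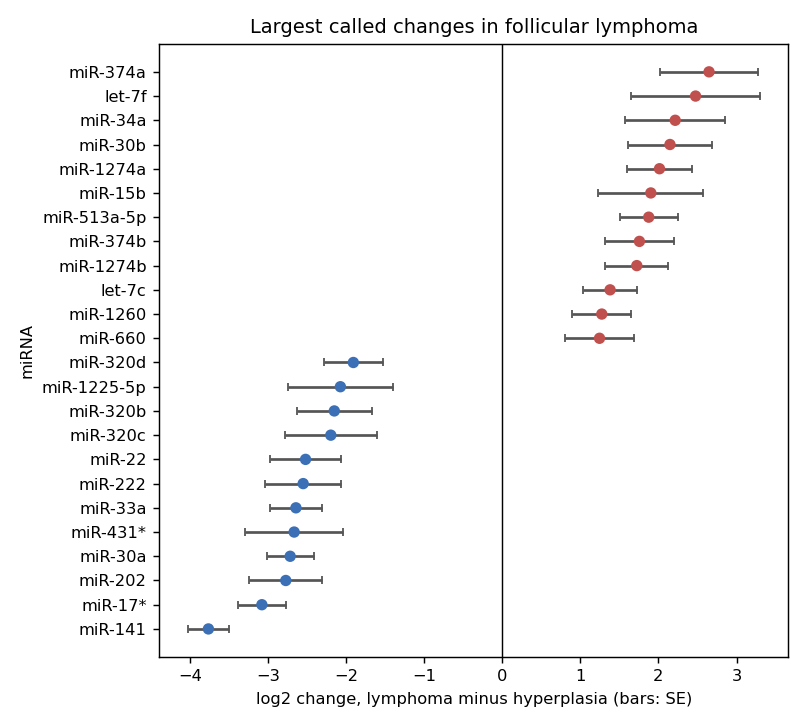
log2 change in lymphoma relative to hyperplasia (points, with SE bars from limma, 18 and 7 arrays) of the 12 miRNAs with the largest called rise and the 12 with the largest called fall. The changes run from -3.76 for miR-141 to 2.65 for miR-374a, and miR-374b lay at the common floor on 4 of 7 hyperplasia arrays, so that its point rests on the floor.

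Among the 12 largest rises, miR-374a changed by 2.65 ± 0.62 on the log2 scale (SE, adjusted p = 0.00274), and it was detected on 16 lymphoma and 3 hyperplasia arrays. Its neighbour miR-374b was also called higher (adjusted p = 0.00432), but it was detected on 15 lymphoma arrays and 1 hyperplasia array and lay at the floor on 4 of 7 hyperplasia arrays, so no fold is given. The change of miR-30b was 2.15 ± 0.54 (adjusted p = 0.00432), with 14 of 18 lymphoma arrays above the highest hyperplasia array. miR-513a-5p, of a miRNA cluster on the X chromosome and at the floor on 3 of 7 hyperplasia arrays, rose 3.67-fold (adjusted p = 0.000592), and miR-660 rose 2.37-fold (adjusted p = 0.0428). miR-513a-5p and miR-660 were detected on 3 and 4 hyperplasia arrays. Their hyperplasia means (-6.87 and -6.63) also lay below the mean limit of these arrays (-5.45), so their folds are uncertain. miR-1274a, miR-1274b and miR-1260, entries that overlap tRNA sequences, rose by 4.04-fold, 3.30-fold and 2.42-fold, and for each of them 17 of 18 lymphoma arrays exceeded the highest hyperplasia array. miR-15b, a relative of miR-16 that represses BCL2, rose 3.74-fold (adjusted p = 0.0447). Its call was lost in 18 of the 25 fits that left out 1 array (adjusted p up to 0.0937), and that of miR-660 in 14 (up to 0.101). The call of let-7f was lost without hyperplasia replicate 1, 3, 5, 6 or 8 (adjusted p = 0.0502, 0.0671, 0.0709, 0.0778 and 0.0569). With normexp, the changes of miR-374a, miR-374b, miR-34a, miR-513a-5p, miR-660 and let-7c turned to -0.40, -1.02, -0.43, -0.88, -1.02 and -0.81, against that setting's median of -1.14. With array brightness as a covariate, miR-1274a, miR-1274b and miR-513a-5p kept their call and the other 9 lost it, let-7f changing by 0.013.

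Among the 12 largest falls, miR-141 changed by -3.76 ± 0.26 (SE, adjusted p = 7.96e-11) and miR-17* by -3.08 ± 0.31 (adjusted p = 7.26e-08), and they lay below the lowest hyperplasia array on 18 and 17 of the 18 lymphoma arrays. miR-30a fell by 2.72 on the log2 scale (adjusted p = 2.61e-07), and miR-33a, which lies within the SREBF2 gene and regulates cholesterol export, fell by 2.64 (adjusted p = 1.56e-06). miR-202 and miR-431* were 6.84-fold and 6.35-fold higher in hyperplasia and lay at the floor on 8 and 6 of 18 lymphoma arrays. miR-222, which represses the cell cycle inhibitor CDKN1B, changed by -2.55 (adjusted p = 0.000457), and miR-22 by -2.52 (adjusted p = 0.000276). The near-identical miR-320b, miR-320c and miR-320d were 4.44-fold, 4.58-fold and 3.75-fold higher in hyperplasia, and probes of this family may share signal. miR-1225-5p, a GC-rich miRNA whose signal can reflect RNA quality, was 4.21-fold higher in hyperplasia (adjusted p = 0.0296). Its call was lost without hyperplasia replicate 1, 6 or 8 (adjusted p = 0.0631, 0.0674 and 0.0604), and its change was 0.032 without scaling and 0.035 with array brightness as a covariate. miR-320d changed by 0.20 without scaling, where the median of all miRNAs was 0.53. With brightness as a covariate 8 of the 12 kept their call, and miR-431*, miR-320b, miR-320c and miR-1225-5p lost it.

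**Figure D3:**
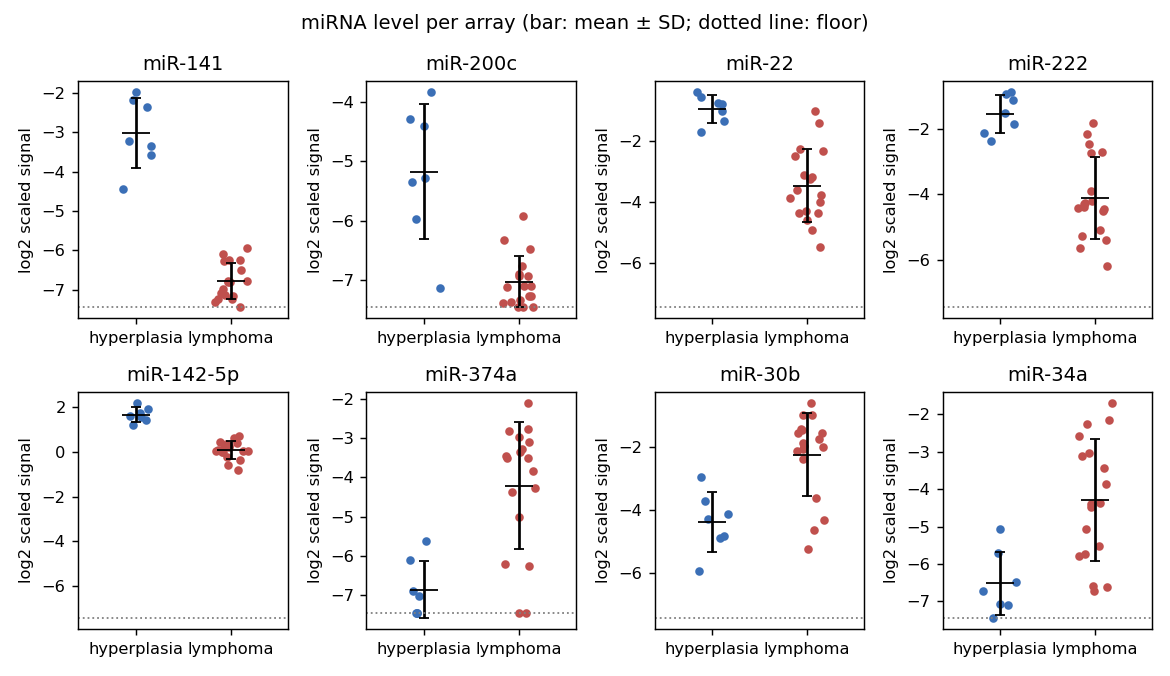
log2 scaled signal of 8 miRNAs on each array (points) in hyperplasia (7) and lymphoma (18), with mean and SD (bars) and the common floor at -7.45 (dotted line). miR-141 lies below the lowest hyperplasia array on all 18 lymphoma arrays, and miR-30b lies above the highest on 14.

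The cluster from miR-17 to miR-92a and its paralogs, which promote B cell growth, had 17 tested members, of which 4 fell (4 adjusted over the list alone) and 13 did not pass the test. Among the 13 was miR-17, the other arm of the miR-17* hairpin, which changed by 0.14 ± 0.36 (SE, limma adjusted p = 0.815). The called members were miR-17*, miR-92a (2.67-fold higher in hyperplasia), miR-106b (1.97-fold) and miR-25 (1.46-fold). As a list they did not pass limma's camera test (adjusted p = 0.139), and their mean relative to other miRNAs was -0.23, but 0.44 without scaling. Without scaling, miR-92a, miR-106b and miR-25 turned to 0.69, 1.13 and 1.56, above that setting's median of 0.53, and in the authors' value table to 0.029, 0.49 and 0.92, below its median of 1.005. The call of miR-25 was lost without hyperplasia replicate 1, 3 or 8 (adjusted p = 0.0507, 0.0671 and 0.0716). The let-7 family had 9 tested members: let-7f and let-7c rose, let-7i fell 1.61-fold (but changed by 1.42 without scaling), and 6 did not pass, while adjusted over the list alone 5 rose and 1 fell. The family rose relative to other miRNAs (camera adjusted p = 0.0208), a call that was lost with adjusted p = 0.559 with an estimated correlation and with adjusted p = 0.0536 without hyperplasia replicate 6. The family did not pass fry (adjusted p = 0.0867). With array brightness as a covariate its relative mean turned from 1.22 to -0.20. The near-identical let-7 probes may share signal.

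Of 8 tested members of the miR-30 family, miR-30b rose and 5 fell, with the same counts adjusted over the list alone. Among those that fell were miR-30a, miR-30e (2.48-fold higher in hyperplasia, adjusted p = 2.42e-05) and miR-30e* (2.18-fold, adjusted p = 0.00274), which turned to 0.79 and 1.16 without scaling. The list did not pass camera (adjusted p = 0.119), with a relative mean of -0.40 that became 0.17 without scaling. The miR-15/16 family had 6 tested members, of which miR-15b and miR-195 rose and miR-497 fell. miR-195 lay at the floor on 4 of 7 hyperplasia arrays and miR-497 on 14 of 18 lymphoma arrays, so no fold is given for them. Adjusted over the list alone, 3 rose and 1 fell, and camera gave adjusted p = 0.407, which became adjusted p = 0.0170 without the 5 arrays that stood apart. miR-195 lost its call in 19 of 25 fits that left out 1 array (adjusted p up to 0.103). miR-16 itself changed by 1.49 ± 0.60 (SE) and did not pass the test (adjusted p = 0.0715), but did so without lymphoma replicate 8, 9 or 15 (adjusted p = 0.00535, 0.0307 and 0.0475). In the miR-29 family of 7, miR-29c* rose 1.89-fold and miR-29a* fell, with the same counts adjusted over the list alone (camera adjusted p = 0.818), miR-29a* lying at the floor on 12 of 18 lymphoma arrays. The hyperplasia mean of miR-29c* (-6.54) lay below the mean limit of these arrays (-5.45), so its fold is uncertain. miR-29a, miR-29b and miR-29c were detected on all arrays and did not pass the test. They changed by 0.25, -0.15 and 0.24 (limma adjusted p = 0.335, 0.674 and 0.481).

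Among 11 tested miRNAs of B cell differentiation and immune activation, 5 fell, among them miR-222, miR-22, miR-342-3p (2.54-fold higher in hyperplasia, adjusted p = 0.00177) and miR-21 (2.02-fold, adjusted p = 0.00852). Without scaling, miR-342-3p and miR-21 turned to 0.76 and 1.09, above that setting's median of 0.53, and in the authors' value table to 0.17 and 0.45, below its median of 1.005. Adjusted over the list alone, 6 fell and 1 rose. The list did not pass camera (adjusted p = 0.119), its relative mean being -0.79, and 0.13 without scaling. Of 8 germinal centre B cell miRNAs, miR-181a and miR-181b, which act in lymphocyte development, were 3.36-fold higher in hyperplasia each (adjusted p = 0.00142 and 0.00302), and miR-28-3p was 1.84-fold higher (adjusted p = 0.0165). Without scaling they turned to 0.36, 0.36 and 0.12, below that setting's median of 0.53, and with brightness as a covariate all 3 lost their call (changes of -0.81, -0.53 and -0.090, adjusted p = 0.0904, 0.237 and 0.755). The same 3 were called adjusted over the list alone, and camera gave adjusted p = 0.386. The call of miR-28-3p, whose 4 probes ranged from -1.90 to 0.05 in log2 change, was lost without hyperplasia replicate 6 (adjusted p = 0.0655).

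The 22 tested MYC-repressed miRNAs went both ways: 3 rose, among them miR-30b and miR-34a, and 4 fell, among them miR-22, miR-30a and miR-30e. Adjusted over the list alone 6 rose and 5 fell, and camera gave adjusted p = 0.407. The list passed camera in opposite directions under other settings: lower with brightness as a covariate (relative mean -0.70, adjusted p = 0.00142) and higher without the 5 arrays that stood apart (0.60, adjusted p = 0.0170). Of 11 tested miRNAs named in earlier lymphoma work, 3 were called higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.880). Those called higher were miR-34a, miR-9 and miR-9*, and those called lower were miR-21, miR-301a (2.33-fold higher in hyperplasia, but 0.85 on the log2 scale without scaling) and miR-338-3p (adjusted p = 5.86e-06, at the floor on 10 of 18 lymphoma arrays). miR-9 was detected on 14 and miR-9* on 13 lymphoma arrays and neither on any of the 7 hyperplasia arrays, and no fold is given, because the mean limit used for a bound (-5.45 on the log2 scale) lay above their lymphoma means of -6.71 and -6.34. Both calls were lost without a filter on dim miRNAs (adjusted p = 0.0849 and 0.0508). The p53-induced miR-34 and miR-192 families had 6 tested members, of which miR-34a and miR-192 rose, also adjusted over the list alone, miR-192 lying at the floor on 4 of 7 hyperplasia arrays. As a list they rose with camera adjusted p = 0.0330, which became adjusted p = 0.477 with an estimated correlation. The list lost its call without hyperplasia replicate 6 or 8 (adjusted p = 0.0536 and 0.0576), and miR-192 lost its call in 18 of 25 such fits (adjusted p up to 0.0864). Of 4 tested miRNAs of the Xq27 cluster, miR-513a-5p rose, also adjusted over the list alone (camera adjusted p = 0.139). Of 7 tested miRNAs of the imprinted cluster at 14q32, limma called 0, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.989).

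Markers of epithelial cells fell as a group in lymphoma: all 4 tested members were lower, with 4 called adjusted over the list alone (camera adjusted p = 0.000475). With an estimated correlation the list gave adjusted p = 0.385. Besides miR-141, miR-200c was 3.61-fold higher in hyperplasia (adjusted p = 7.72e-05), and miR-200b was called lower in lymphoma (adjusted p = 0.000276), where it lay at the floor on 17 of 18 arrays. miR-200a, detected on 3 hyperplasia and 4 lymphoma arrays and at the common floor on all 18 lymphoma arrays, had an adjusted p of 0.0121. miR-203 was detected on 3 hyperplasia arrays and 0 of 18 lymphoma arrays and was called lower in lymphoma (adjusted p = 0.00717, limma over all 851 human names, where miR-205 had adjusted p = 8.92e-07). No bound is given for miR-203, because its hyperplasia mean (-5.77 on the log2 scale) lay below the mean limit of the hyperplasia arrays (-5.45). The list lay below other miRNAs under all 6 scaling alternatives, by -0.47 to -3.07.

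Of 2 tested T cell markers, too few for camera, miR-342-3p, which B cells also express, fell, also adjusted over the list alone. Of 5 tested myeloid markers miR-24, which is not restricted to myeloid cells, was 2.26-fold higher in hyperplasia (adjusted p = 0.00274) but changed by 0.96 on the log2 scale without scaling, with 2 lower adjusted over the list alone (camera adjusted p = 0.407). Of 6 tested stromal and endothelial markers, miR-497 was called lower in lymphoma, also adjusted over the list alone (camera adjusted p = 0.818). Of 3 tested red cell and platelet markers, miR-486-5p was 2.37-fold higher in hyperplasia, also adjusted over the list alone (camera adjusted p = 0.637). Without scaling miR-486-5p changed by 0.91 on the log2 scale, and its call was lost in 15 of 25 fits that left out 1 array (adjusted p up to 0.124). Of 22 tested members of the list named GC-rich miRNAs, which can be bright in degraded or scarce RNA, miR-1225-5p and miR-1246 (3.20-fold higher in hyperplasia, adjusted p = 0.0165) fell. The base content of the members was not checked. Adjusted over the list alone, limma called 0 of the 22, and camera gave adjusted p = 0.407. This list too passed camera in opposite directions under other settings: higher with brightness as a covariate (relative mean 0.92, adjusted p = 0.00768) and lower without the 5 arrays that stood apart (-1.25, adjusted p = 0.00946). The call of miR-1246 was lost without hyperplasia replicate 1 (adjusted p = 0.0631).

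The highest total signals in both groups included miR-142-3p, a haematopoietic miRNA, and miR-720 and miR-923, entries derived from tRNA and ribosomal RNA. None of these 3 passed the test, with log2 changes of -0.22 ± 0.57, 0.31 ± 0.40 and 0.32 ± 0.66 (SE), but with brightness as a covariate they passed it (-2.00, 1.41 and 1.89, adjusted p = 0.0011, 0.00402 and 0.0315). miR-142-5p, the other arm of the miR-142 hairpin and among the 5 highest in hyperplasia, was 3.02-fold higher there (adjusted p = 1.48e-07) and lay below the lowest hyperplasia array on all 18 lymphoma arrays. Without scaling it turned to 0.51, against that setting's median of 0.53. Lymphoma samples lay 0.867 ± 0.380 (SD) log2 units from the mean of their group and hyperplasia samples 0.590 ± 0.128, which did not pass an exact permutation test (two-sided p = 0.0595). Among the lymphoma samples alone, limma called 3 miRNAs between the 3 slides, with 69 at an unadjusted p under 0.05.

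With the slide as a random block, 6 miRNAs were higher and 38 lower, all among those above. Of the 12 largest rises 6 kept their call (miR-374a, miR-30b, miR-1274a, miR-513a-5p, miR-374b and miR-1274b), as did 11 of the 12 largest falls, all except miR-1225-5p. This fit can learn differences between slides from the lymphoma slides only (correlation within slides 0.107). It cannot take out an effect of the hyperplasia slide. Against hyperplasia, the lymphoma arrays of slide 2 alone gave 40 higher and 84 lower miRNAs, those of slide 3 gave 1 and 16, and those of slide 4 gave 20 and 42. Of the 12 largest rises and 12 largest falls, all were called on slide 2, 1 and 5 on slide 3, and 11 and 11 on slide 4, but these miRNAs were chosen on the same arrays and the 3 slides share the 7 hyperplasia arrays. With array brightness as a covariate 4 of the 20 higher and 29 of the 56 lower miRNAs kept their call, among 60 higher and 44 lower in all. Besides those already given, miR-195, miR-29a*, miR-29c*, miR-301a, miR-192, miR-486-5p, miR-1246 and the p53-induced list lost their call in that fit. Since hyperplasia was measured on 1 slide only, its slide cannot be separated from its biology.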

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

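The tests of the epithelial miRNAs and of the spike-in were chosen only after the result had been seen. The test of how signal follows array brightness and the count of other splits were written before.

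Chance marks about 1 in 20 groups of values as holding an array far from the others, and of 59 groups of hyperplasia values tested 2 were marked. The log2 level of miR-374b was -5.67 in hyperplasia replicate 9, with the nearest array at -7.04. The log2 level of miR-342-3p was 0.587 in hyperplasia replicate 3, with the nearest array at -0.0043.

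Random splits did not reach the count of called miRNAs: of 100 splits of the 25 arrays into 7 and 18, 1 (the real one, 76 calls) gave as many, and the highest of the others gave 1. Setting the 7 arrays of slide 4 against the rest also gave 1. In all splits but the real one, arrays of both groups shared a side, which widens the spread within it and lowers the count. The random splits also cut across slides, so they cannot exclude that differences between slides give such a count. They do not bear on the slide of the hyperplasia arrays, which coincides with the group.

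Epithelial miRNAs were higher in hyperplasia although B cells had been sorted. A candidate explanation is RNA of epithelial cells in the hyperplasia samples: miR-205, outside the 4 called members, was detected on 6 of 7 hyperplasia arrays and followed their mean over these arrays (Spearman rho = 0.929, exact permutation p = 0.00675; Pearson r = 0.98, exact permutation p = 0.00119, and 0.96 without the 2 arrays farthest from the median). These 2 p-values were a family of 1 relation and were not adjusted. The tables argue against array brightness as the whole cause, since without any scaling the mean of the 7 markers was still lower on the brighter lymphoma arrays (-0.82 on the log2 scale, exact permutation p = 0.00329). Slide and scan batch stay open, because 0 slides held both groups, and so does a difference between the B cells themselves, which was not tested.

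The 56 miRNAs called lower could in part be miRNAs whose signal does not follow the brightness of the array, so that scaling lowers them on the brighter lymphoma arrays. Among the 34 of them detected on all arrays, the median within-group slope of unscaled log2 signal on the log2 scale factor was 0.554 (95% bootstrap interval 0.408 to 0.806), and it was 0.651 for the 42 detected everywhere and not called. The bootstrap drew miRNAs and not arrays, so its interval leaves out the spread between arrays. The scale factor came from probes well above background on all arrays, which can belong to these same miRNAs. The interval includes both slopes that were set as bounds, so this explanation and a fall in lymphoma cannot be told apart for these miRNAs as a set. Of the 34, 14 had a slope under 0.5, among them miR-431* (-0.16), miR-1225-5p (0), miR-202 (0.20), miR-320c (0.28), miR-222 (0.39) and miR-22 (0.39). The slopes of miR-17* (0.52) and miR-141 (0.81) were higher. Without scaling, 16 of the 56 still had a change below 0, where the median of all tested miRNAs was 0.53. With brightness as a covariate 29 of the 56 were still called lower, and 4 of the 20 higher miRNAs were still called higher. Slide and scan batch remain open here too.

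The brighter lymphoma arrays may reflect hybridization and scan strength or a larger share of miRNA in their RNA. The hybridization spike-in differed by 1.04 of the 2.11 log2 units by which the scale factor differed. The remaining 1.06 did not pass an exact permutation test (p = 0.0606), so the explanations cannot be told apart, with the groups on different slides.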

How the results depend on the processing

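Keeping spots with outlier flags, array brightness as a covariate, leaving out 3 or 5 arrays that stood apart, the estimated correlation and calls of at least 2-fold were tried only after the data had been seen; the other alternatives were set in advance. Where values moved, the cause was not tested. Signal over background is the limit for the dim arrays, where miRNAs at the floor carry no order.

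Against 20 higher and 56 lower miRNAs and 3 list calls, the number of higher and lower miRNAs was 4 and 15 with the percentile over all probes, 32 and 34 with quantile normalization (1 list), 116 and 5 without scaling (1 list), 7 and 309 with normexp, 94 and 25 with the deposited total signals (1 list) and 137 and 11 with the authors' value table (1 list). It was 4 and 37 for miRNAs detected on all arrays (0 lists called by camera, with fewer members tested), 12 higher without a filter, 33 higher with the lower floor, 12 and 99 with flagged spots kept, and 13 higher with a fitted change of 2-fold or more, including miR-9* and miR-374b, for which no fold is given. Array brightness as a covariate gave 60 higher, of which 4 were among the 20, and 44 lower, of which 29 were among the 56. It called 8 lists, with GC-rich miRNAs higher and the miR-17, miR-30, MYC-repressed, germinal centre, B cell differentiation, myeloid and epithelial lists lower. Leaving out 3 arrays that stood apart gave 35 higher, and leaving out 5 gave 43 and 100 (6 lists), with miR-923 at -0.33 and miR-142-3p at 0.23. The slide as a random block gave 6 higher (1 list). Slide 2 alone gave 40 higher (5 lists), and slide 3 alone 1 and 16 (5 lists), with fewer arrays. With an estimated correlation 0 lists passed camera. Trended and robust moderation gave 20 and 56, of which 19 and 54 were among the main calls. In that fit 2 of the miRNAs that the rule names and 1 list lost their call. Leaving out 1 array gave 13 to 31 higher, 49 to 67 lower, 1 to 3 lists (1 without hyperplasia replicate 6), and a difference in detected miRNAs of 84.3 to 115. The distance from the group mean differed by 0.49 and passed the exact permutation test (p = 0.0229) for miRNAs detected on all arrays. Between lymphoma slides, limma called 0 miRNAs after quantile normalization and 1 among those detected on all arrays.

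The replicate numbers do not pair the samples: of 7 shared numbers, 2 had a correlation of deviations above 0.1 (range -0.571 to 0.554) and 2 correlated best with their own number. With the replicate number as a block, 1 miRNA was higher and 27 lower, 1 list was called, and miR-923 changed by -0.081.

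Directions turned, on the log2 scale and before any shift of the median is taken off, as follows for the lists and for the miRNAs that the rule names. Of other called miRNAs named in the text, miR-130b and miR-33b* changed by 0.27 and 0.19 without scaling, and miR-9 and miR-9* by -1.05 and -1.08 with normexp. Without scaling, the changes were miR-1225-5p 0.032, miR-320d 0.20, miR-21 1.09, miR-142-3p 1.88, miR-142-5p 0.51, miR-106b 1.13, miR-92a 0.69, miR-25 1.56, let-7i 1.42, miR-497 0.17, miR-29a* 0.16, miR-30e 0.79, miR-30e* 1.16, miR-181a 0.36, miR-181b 0.36, miR-28-3p 0.12, miR-342-3p 0.76, miR-301a 0.85, miR-24 0.96, miR-486-5p 0.91 and miR-1246 0.42. In the authors' value table they were miR-21 0.45, miR-142-3p 1.21, miR-106b 0.49, miR-92a 0.029, miR-25 0.92, let-7i 0.73, miR-29a* 0.16, miR-30e 0.23, miR-30e* 0.60, miR-342-3p 0.17, miR-301a 0.62, miR-24 0.27 and miR-486-5p 0.71. With the deposited total signals they were miR-142-3p 0.38, miR-25 0.092, miR-301a 0.055 and miR-486-5p 0.15, and with the percentile over all probes miR-142-3p 0.54, miR-25 0.22 and let-7i 0.081. With normexp they were miR-374a -0.40, miR-34a -0.43, miR-513a-5p -0.88, miR-374b -1.02, let-7c -0.81, miR-660 -1.02, miR-195 -1.17, miR-29c* -1.08 and miR-192 -1.16, and camera placed the p53-induced list lower, with a relative mean of 0.0047. miR-923 changed by -0.30 with quantile normalization and by -1.26 on slide 2 alone, where miR-142-3p changed by 0.75. With brightness as a covariate, miR-1225-5p changed by 0.035, miR-16 by -0.29 and miR-195 by -0.079, and the relative means of let-7, MYC-repressed and GC-rich miRNAs were -0.20, -0.70 and 0.92 (adjusted p = 0.431, 0.00142 and 0.00768). The single miRNAs that the rule names kept their direction under the slide block, slides 3 and 4 alone (which share the hyperplasia arrays), the lower floor, trended moderation, no filter, and whichever array was left out.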

Other observations

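The families and the tRNA-derived entries below were chosen, and the tRNA test was written, only after the values had been seen.

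The following are counts and medians of small miRNA families, with no test of a family as a set. All 4 tested members of the miR-320 family fell (median log2 change -2.03), as did 3 of 4 of the miR-181 family (median -1.44) and 3 of 4 of the joint miR-130 and miR-301 family (median -1.09, with miR-301b at the common floor on 10 of 18 lymphoma arrays), where miR-130b changed by -1.83 ± 0.38 (SE, limma adjusted p = 0.000943) and miR-130a by -0.30 ± 0.28 (adjusted p = 0.471). Without scaling miR-130b changed by 0.27, below that setting's median of 0.53. Of the miR-33 entries, miR-33a and miR-33b* were tested and both fell (median -2.08). miR-33b* is the arm opposite miR-33b, which was not tested. Relative to the median of all miRNAs, each of these families stayed below 0 under all 6 scaling alternatives, the highest values being -0.45 for miR-320, -0.0027 for miR-181, -0.12 for the joint miR-130 and miR-301 family and -0.35 for miR-33. Both members of the miR-374 family were called higher, miR-374b lying at the floor on 4 of 7 hyperplasia arrays. Of 12 tested miRNAs of the cluster at Xp11.23, miR-660 alone was called (median 0.10, relative values from -0.01 with normexp to 1.16). Of the paired miRNAs miR-221 and miR-222, miR-222 was called, and miR-221 changed by -0.60 ± 0.26 (adjusted p = 0.101).

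Entries that overlap tRNA sequences might move as a group in lymphoma. Of 6 such entries (miR-720, miR-1260, miR-1274a, miR-1274b, miR-1280 and miR-1308), 3 were called higher, with a median change of 0.79. Camera gave p = 0.0217 with the preset correlation and p = 0.229 with an estimated correlation, so the data do not settle it. miR-1308 and miR-1280 changed by -0.73 ± 0.35 and -0.35 ± 0.35 (SE), and neither passed the test.

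Of 88 viral miRNA names, 34 were detected on no array and 2 on all arrays. Among 21 tested, limma called 0 higher in lymphoma (0 at an unadjusted p under 0.05) and 2 lower (3 at an unadjusted p under 0.05).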
